A study of Rattus norvegicus with 4 samples.

How the data were processed

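Total RNA of NR8383 cells was labelled with Cy3 and hybridised to single-colour Agilent rat arrays, per the labels' protocols. Each of the 4 exposed cultures had 1 array. The intensity values were made by the authors with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. Per the file headers, each spot's processed signal intensity was background-subtracted and spatially detrended within its array, with no scaling between arrays. The other columns used were, per the file headers, the median spot intensity, the median local background intensity, and flags of 0 or 1 for being well above background, positive and significant, saturated or an outlier within the spot or among repeat spots. How the authors normalized between arrays or tested genes is not given in the sources used here.

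The 4 samples were put in 1 group by their treatment label, and the replicate number came from their title. The study's design gives 4 biological replicates per condition. Control cultures were not analysed here, so no comparison between conditions, no paired fit and no regrouping of samples was made. No pair of arrays held identical values.

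Control spots were left out, which leaves 58717 non-control spots of 62976 before outlier removal. Spots marked as outliers were left out too, except where every spot of a probe on an array was marked. Such spots were kept, so a marked spot of a probe with 1 spot per array stayed in its value. The outlier marks covered 1.13%, 1.21%, 1.21% and 1.63% of non-control spots on replicates 1 to 4. Log2 of the processed signal was set relative to each array's 75th percentile over non-control spots not marked as outliers, and repeat spots were averaged. A probe with repeat spots thus counted once per spot in that percentile. Probes numbered 45598. The files hold no gene names, so a probe's accession was matched without its version to the RefSeq gene table of the GRCr8 assembly, which was used for names only. A symbol was found for 21109 probes, none matched several, and 24489 stayed unnamed, of which 6958 carry Ensembl transcript accessions. The array's grid is annotated on rn4 per the file headers, and no coordinates are given. A gene was represented by the probe above background on most arrays, with ties broken by the highest mean signal. The spike-in standard curves had slopes of 0.96, 0.909, 0.945 and 0.961 and R² of 0.988, 0.988, 0.991 and 0.986 on replicates 1 to 4.

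Tests, gene groups and the rule for named genes were fixed before the data were examined. The rule took the first 4 measured members of each of 28 gene groups in list order with their values, other members as above background on all, some or no arrays or where they passed the test of excess spread, the 10 genes of lowest adjusted p in that test, and genes saturated on all arrays, of which there were 0. The groups cover macrophage genes, alveolar macrophage and lipid handling, iron and haem handling, antioxidant and NRF2, ferroptosis, inflammatory cytokines and NF-kB, inflammasome, immediate early, scavenging and phagocytosis, lysosome, heat shock, unfolded protein and integrated stress, metallothionein and zinc, p53 and DNA damage, cell cycle, interferon, cholesterol synthesis, glycolysis and hypoxia, matrix remodelling, ribosomal proteins, respiration, housekeeping, and markers of T and NK cells, B cells, granulocytes and mast cells, lung epithelium, endothelium and fibroblasts, and other tissues. Of 527 list entries, 495 were on the array, and 4 symbols were updated to the table's current ones.

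The share of each group above background on all 4 arrays was compared with all other named genes by two-sided Fisher's exact test. Excess spread was tested with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8): each gene's variance between the 4 arrays was set against a prior variance fitted robustly as a trend on mean level (prior degrees of freedom 9.16), in an upper-tail F test over the 8376 genes above background on all 4 arrays. For the 22 groups with at least 5 such members, the median SD of the members (two-sided) and the SD over arrays of their mean deviation (upper tail) were each set against 10000 random lists of the same size matched on mean level in 20 bins. Adjusted p-values are Benjamini-Hochberg within each family, with a threshold of 0.05. The spread between arrays was set beside that of repeat spots as a ratio. The planned sign-flip permutation test of this ratio was run, and its p is not given, because probes on the same 4 arrays are not independent and a mean of 10 spots varies less than a single spot. The ratio used the 1036 of 1350 probes spotted 10 times that were well above background on all arrays; probes spotted 2 times were not used.

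On simulated data with the levels of the 8376 genes, the excess spread test called 64% of 100 genes given 5 times the SD and 93% of 100 given 10 times the SD, with 5 unchanged genes called. Of 50 lists simulated without shared movement, 1 had an unadjusted p under 0.05 for movement and 3 for spread. The simulated genes varied independently of one another, so these counts do not show the error rate where genes vary together. A list with array shifts of SD 0.13 had a movement p of 0.0035, and one with shifts of SD 0.04 a p of 0.045.

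Alternatives were the 75th percentile over probes above background on all arrays, quantile normalization, cyclic loess, normexp background correction with an offset of 50, the positive and significant mark in place of well above background, the mean over a gene's probes, genes above background on at least 1 array, a constant or a non-robust prior variance, 10 bins, other list statistics, saturated probes left out, and each array left out in turn. Fewer probes were well above background than below it on each array, where the percentile over probes above background is often preferred; the scaling fixed in advance was kept, with that one as an alternative. Normexp was planned on the mean spot intensity and was run on the median spot intensity, the column the files hold. Quantile-normalized values were shifted by 1 constant to the mean of the main values. An alternative chosen after seeing the data left out genes whose probe lay in a streak of bright spots. A bright spot was that of a probe with 1 spot per array whose log2 level on 1 array was above 0, the 75th percentile, and exceeded the highest of the other arrays by more than 2, and a streak had another such spot on the same array within 10 rows and 3 columns.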

Results

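Gene expression was measured in NR8383, an alveolar macrophage cell line established from rat lung lavage, after exposure to 2 µg/mL of the Fe2O3 particle NRCWE018 for 4 h. The study compared exposed with control cultures, 4 biological replicates of each. The 4 exposed cultures are described here, each on 1 single-colour array, and the control cultures were not analysed here. No value below is therefore an effect of the particles. The values show which genes and gene groups were above background in exposed macrophages, and which differed between the 4 exposed cultures. The 75th percentile of the processed signal was 1072, 984.3, 1082 and 756.5 on replicates 1 to 4, and the median local background lay between 41 and 46. Of 45598 probes, 40.2%, 41.2%, 40.8% and 37.8% were well above background on replicates 1 to 4. No spot was saturated. With 4 arrays, the number of arrays limits the precision.

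Of 16581 named genes, 8376 (50.5%) were above background on all 4 arrays, 1069 (6.45%) on some and 7136 (43.0%) on none. Levels of single genes are given as log2 signal relative to the array's 75th percentile, as mean ± SD over n = 4 arrays. A level of one probe cannot be set against that of another, so the gene groups fixed before the data were examined are described by how many members were above background on all 4 arrays.

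Macrophage genes were present on every array. Of 27 measured macrophage genes, 20 were above background on all 4 arrays, among them the lysosomal marker Cd68 (4.96 ± 0.20), the CSF1 receptor Csf1r (-0.40 ± 0.11), lysozyme Lyz2 (7.17 ± 0.14) and the lineage transcription factor Spi1 (0.88 ± 0.14). The complement genes C1qa, C1qb and C1qc, the haemoglobin-haptoglobin receptor Cd163, Adgre1 and Cd74 were above background on no array, and Mertk on some. In the group of alveolar macrophage and lipid-handling genes, 13 of 16 were above background, including the nuclear receptor Pparg (4.15 ± 0.14) and the fatty acid binding proteins Fabp4 and Fabp5 (6.38 ± 0.08). The scavenger receptor Marco, which is characteristic of alveolar macrophages, was above background on no array, as were Car4 and Chi3l1. Of 18 genes of scavenging and phagocytosis, 13 were above background, with Msr1 at -3.66 ± 0.56, Scarb1 at 1.48 ± 0.23 and the fatty acid and lipoprotein receptor Cd36 at 4.84 ± 0.17. All 23 lysosomal genes were above background, among them Lamp1 (3.26 ± 0.14) and the protease cathepsin D, Ctsd (7.17 ± 0.16).

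Ferritin and transferrin receptor genes were above background, whereas the iron exporter gene was not. Of 30 measured genes of iron and haem handling, 22 were above background on all 4 arrays, including the ferritin subunits Fth1 (7.56 ± 0.19) and Ftl1 (7.77 ± 0.13) and the transferrin receptor Tfrc (1.20 ± 0.29). The haem oxygenase Hmox1 was also above background on all 4. The exporter Slc40a1 (ferroportin), its peptide regulator Hamp, and Steap4, Cybrd1 and Cd163 were above background on no array, and Heph, Slc25a37 and Bach1 on some. In the group of antioxidant genes and NRF2 targets, 26 of 27 were above background, with Nqo1 at -1.56 ± 0.05, sulfiredoxin Srxn1 at 3.70 ± 0.22 and thioredoxin reductase Txnrd1 at -0.78 ± 0.31. The exception was Gclm, the modifier subunit of glutathione synthesis. Of 17 genes linked to ferroptosis, an iron-dependent form of cell death, 15 were above background, including Acsl4 (-2.39 ± 0.27), the lipid hydroperoxide-reducing enzyme Gpx4 (7.15 ± 0.07) and the cystine transporter Slc7a11 (-0.72 ± 0.22). Alox15 and Ptgs2 were above background on no array. Of 9 metallothionein and zinc genes, 8 were above background, with Mt1 at 3.40 ± 0.13 and Mt2A at -2.85 ± 0.50.

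Inflammatory genes were above background in part. Of 28 measured cytokine genes and NF-kB targets, 17 were above background on all 4 arrays, among them Tnf (2.65 ± 0.22), Il1b (3.71 ± 0.16) and the neutrophil chemoattractant Cxcl2 (-0.10 ± 0.53). Il6, Cxcl1, Ccl20, Ptgs2, Csf1, Csf2, Il10, Il12b and Il23a were above background on no array, and Nos2 and Lif on some. Of 9 inflammasome genes, 8 were above background, including the sensor Nlrp3 (-1.61 ± 0.28), Casp1 (-0.12 ± 0.25) and Il18 (2.38 ± 0.13). Of 21 immediate early genes, 14 were above background, with Atf3 at 0.74 ± 0.30 and Jun at 0.11 ± 0.15. Egr1 was above background on no array and Fos on 2. In the interferon group, 18 of 21 genes were above background, including Isg15 (-0.60 ± 0.19) and Mx1 (-2.45 ± 0.13), whereas Ifit1 and Ifnb1 were above background on none. In the group of matrix remodelling genes, 8 of 17 were above background, with the macrophage elastase Mmp12 at -1.56 ± 0.85 and Gpnmb at 6.07 ± 0.13. Osteopontin, Spp1, was above background on no array and Timp1 on 2.

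Genes of growth, metabolism and stress responses were above background in most cases. All 22 measured cell cycle genes were, including Mki67 (0.44 ± 0.21) and Cdk1 (4.12 ± 0.09), as were all 17 cholesterol synthesis genes, such as Sqle (1.24 ± 0.15) and Insig1 (2.05 ± 0.16). All 12 heat shock genes, all 23 ribosomal protein genes, all 17 nuclear-encoded respiratory chain genes and all 11 housekeeping genes were above background. Hspa8 lay at 7.03 ± 0.20, Rplp0 at 7.46 ± 0.11, Cox4i1 at 6.60 ± 0.11 and Actb at 6.89 ± 0.24. Of 21 genes of the unfolded protein and integrated stress responses, 19 were above background, among them the stress-induced factors Atf4 (4.57 ± 0.22) and Ddit3, which was at 0.89, 1.67, 1.34 and 0.10 in replicates 1 to 4. In the p53 and DNA damage group, 14 of 16 were, with the cell cycle inhibitor Cdkn1a at 3.08 ± 0.33 and Bax at 3.65 ± 0.14. Of 19 glycolysis and hypoxia genes, 16 were above background, including Slc2a1 (2.67 ± 0.28) and Ldha (6.89 ± 0.13), whereas Vegfa, Egln3 and Hk1 were above background on none.

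Markers of other cell types were mostly below background. Of 13 lung epithelium markers, 1 was above background on all 4 arrays, Foxj1; surfactant genes Sftpc, Sftpb, Sftpa1 and Sftpd, Epcam and Cdh1 were not above it on any array. Of 19 markers of liver, neurons, muscle and other tissues, 1 was above background, Tnnt2. In the T and NK cell group 3 of 12 were (Cd3d, Lck and Nkg7), in the B cell group 1 of 5 (Pax5, -2.17 ± 0.29) and in the granulocyte and mast cell group 2 of 11 (S100a8, -4.38 ± 0.77, and Camp, -0.22 ± 0.14). Of 14 endothelium and fibroblast markers 4 were above background: Pecam1 (-0.51 ± 0.16), Cdh5, Dcn and Vwf.

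**Figure D1:**
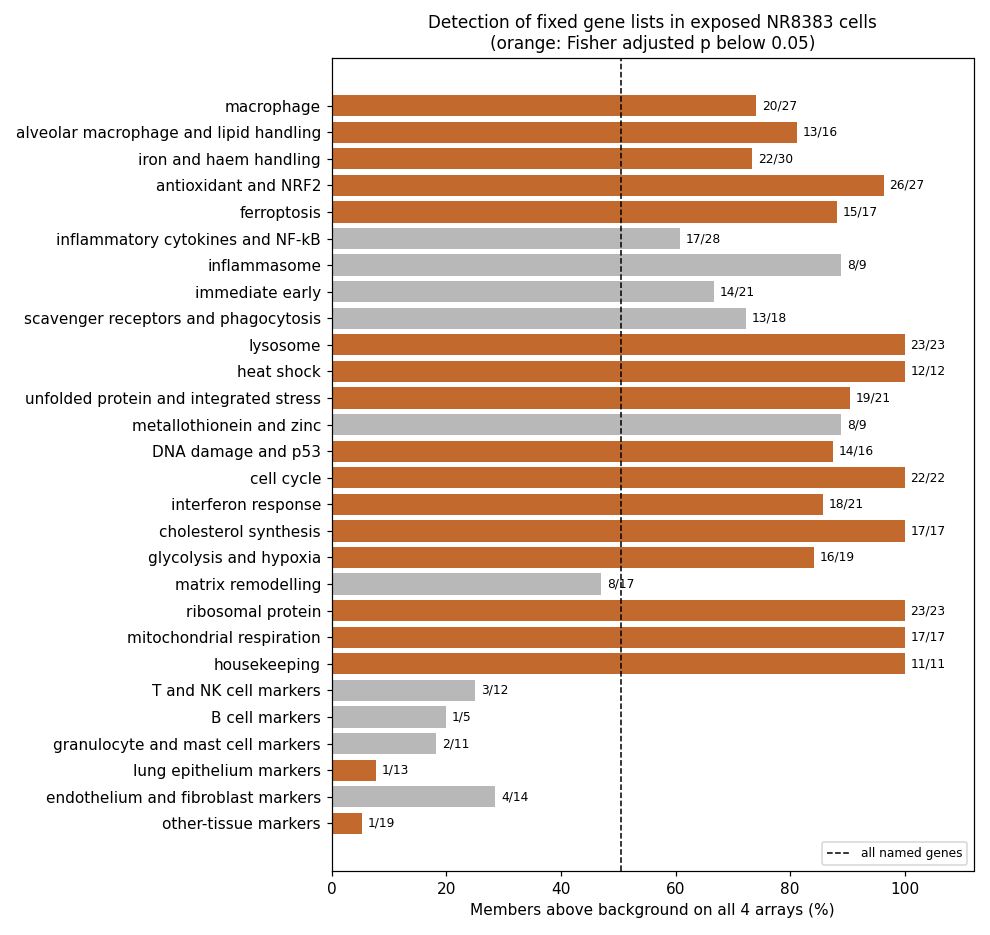
Share of measured genes of each of the 28 gene groups above background on all 4 exposed arrays (horizontal bars, in percent), with the count of members beside each bar, orange bars for an adjusted p under 0.05 and a dashed line for all named genes. All 23 lysosomal genes, but 1 of 13 lung epithelium markers, were above background, against 50.5% of all named genes.

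By two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 28 groups, 18 groups differed from all other named genes in the share above background, 16 with a higher share and 2 with a lower share. The adjusted p was 3.37e-06 for antioxidant genes, cell cycle, lysosome and ribosomal protein genes, 0.0317 for macrophage genes, 0.0332 for alveolar macrophage genes, 0.0283 for iron and haem handling and 0.00508 for ferroptosis genes in this exact test. It was 0.00386 for the lower share of lung epithelium markers and 0.000136 for that of markers of other tissues. The other groups with a higher share ranged from 7.17e-05 for cholesterol synthesis and respiratory chain genes to 0.00829 for p53 and glycolysis genes. The remaining 10 groups did not pass, with adjusted p in the exact test from 0.0521 for inflammasome, metallothionein and granulocyte genes to 0.813 for matrix remodelling; the inflammatory group was at 0.358 and the immediate early group at 0.212. The call for alveolar macrophage genes was lost with the positive and significant mark (adjusted p 0.1 in the exact test) and with genes above background on at least 1 array (0.0942). A probe below background does not show that its gene was not expressed, and genes are not independent replicates. Marco, Gclm, Il6 and Hk1, among others above background on no array, had 1 probe each. Of 3658 genes with more than 1 probe, 862 had probes that disagreed on being above background on all 4 arrays.

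The 4 exposed cultures gave closely similar profiles. Pearson's r over the 8376 genes above background, a correlation across genes, which are not independent replicates, ranged from 0.990 to 0.993 for the 6 pairs of arrays, and the median absolute log2 difference from 0.17 to 0.21. No pair of arrays held identical values. Among 1036 probes spotted 10 times on each array, the SD between array means had a median of 0.14 on the log2 scale and the SD among repeat spots within an array a median of 0.06. The median ratio was 2.06, or 1.31 after normexp background correction. No p is given for it, because probes on the same arrays are not independent. The ratio sets means of up to 10 spots beside single spots. A mean varies less than a single spot, so the ratio understates how far the spread between arrays exceeded spot noise. The spread between arrays holds differences between cultures and between arrays alike. The first principal component (42.4% of the variance) set replicate 4, the array of lowest signal, apart from the others. The 4 arrays lay on 1 slide at 4 positions, so culture and position on the slide cannot be told apart.

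The genes that differed most between the exposed cultures included lipocalin 2 (Lcn2), an innate immune protein that binds iron-carrying siderophores. Its log2 level was 5.13, 4.40, 2.72 and 5.34 in replicates 1 to 4, a range of 2.61, with an adjusted p of 0.00131 in limma's test of variance against genes of like level. The 5.8S ribosomal RNA probe Rn5-8s was at 0.48, 3.28, 1.58 and 2.30 (limma adjusted p 0.0033). In this test 16 of the 8376 genes (0.191%) passed, and 482 had an unadjusted p under 0.05 against 418.8 expected by chance. In 8 of the 10 genes of lowest adjusted p, a single array stood far above the others: Nek4, Rnf44 and Grwd1 on replicate 2, Usp40 on replicate 1, and RGD1359108, Mgat1, Ccdc28b and Brca1 on replicate 4. Nek4 was at 5.92 on replicate 2 and between -3.97 and -3.24 on the others. The spots of Nek4, Usp40, Mgat1, Ccdc28b, Grwd1 and Brca1 lay within 10 rows and 3 columns of another spot with such a single-array excess at a level above the 75th percentile.

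**Figure D2:**
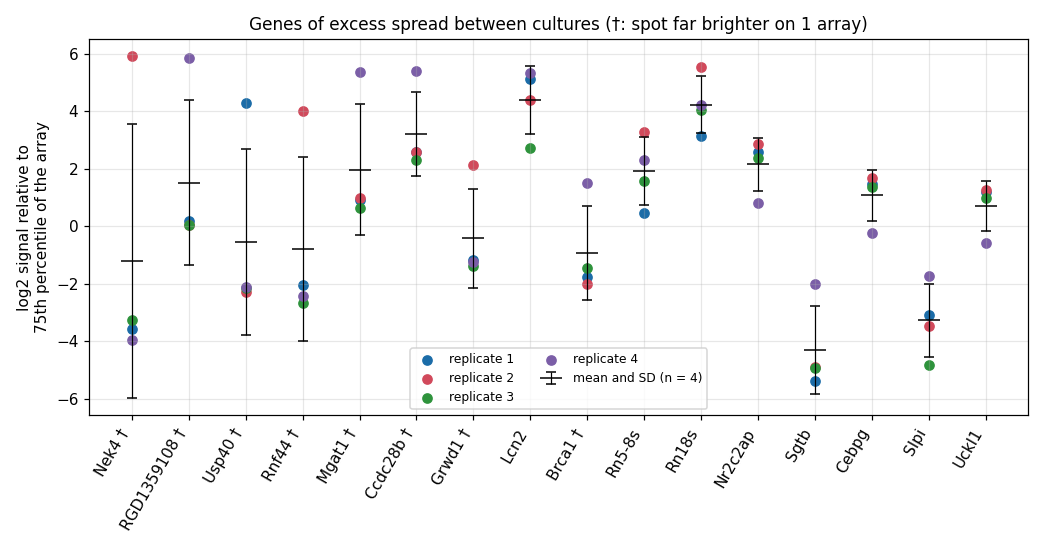
Log2 signal relative to the array's 75th percentile on each of the 4 exposed arrays for the 16 genes whose variance between arrays exceeded that of genes of like level (limma, adjusted p under 0.05), with 1 coloured point per array, a black mark and bar for mean and SD (n = 4), and a dagger for the 8 genes with a spot that exceeded the other arrays by more than 2 at a level above 0. Lcn2 was lowest on replicate 3 at 2.72, and Nek4 was at 5.92 on replicate 2 alone.

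The other 6 genes that passed were Rn18s, Nr2c2ap, Sgtb, Cebpg, Slpi and Uckl1, named after their values were seen. Sgtb also stood above the other arrays on replicate 4, at -2.01 against -5.37, -4.88 and -4.92 in replicates 1 to 3, below the 75th percentile. Slpi, a secreted inhibitor of leukocyte proteases, was at -3.08, -3.45, -4.83 and -1.72 in replicates 1 to 4 (limma adjusted p 0.0469). The transcription factor gene Cebpg was at 1.48, 1.68, 1.37 and -0.24 (limma adjusted p 0.0395). Nr2c2ap and Uckl1 were likewise low on replicate 4 alone, at 0.81 and -0.59. Of the 16 genes, 8 were farthest from their mean on replicate 4, the array of lowest signal. Adjusted over the list alone, 8 list genes passed: Lcn2 in iron handling, Cxcl2 and Ccl4 in the inflammatory group, Ddit3 in the stress response group, Mmp12 and Mmp9 in matrix remodelling, Cox6c in respiration and S100a8 among granulocyte markers. Over all genes, Lcn2 was the only list gene to pass. No gene passed both with all arrays and under every omission of 1 array, and normexp background correction raised the count from 16 to 156. The count was 5 with a constant prior variance, 10 with a prior that was not robust and 7 without replicate 2. Without the genes in streaks of bright spots, an alternative chosen after seeing the data, 6 passed, all of them among the 16.

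**Figure D3:**
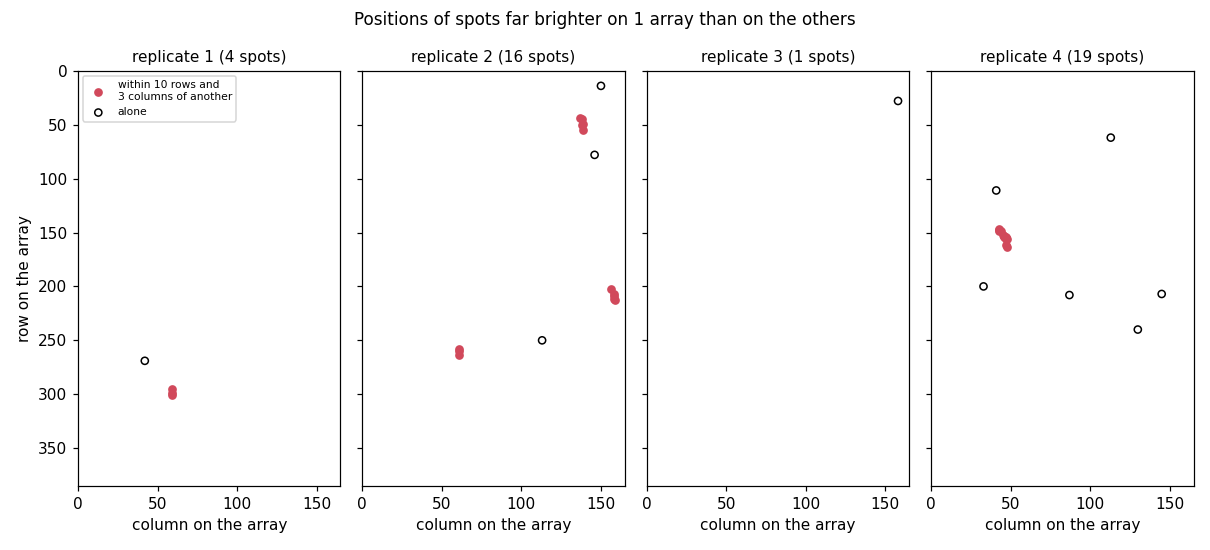
Row and column of the 40 spots, among probes with 1 spot per array, whose log2 level on 1 array was above 0 (the 75th percentile) and exceeded the highest of the other 3 by more than 2, one panel per array, with filled points for spots within 10 rows and 3 columns of another and open points for the rest. There were 4, 16, 1 and 19 such spots on replicates 1 to 4, and 29 of the 40 lay in such clusters.

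The mean levels of the iron and haem handling, inflammatory and matrix remodelling groups differed between the exposed cultures, lowest in replicate 3 and highest in replicate 4, except that replicates 1 and 4 were both at 0.10 for iron genes after quantile normalization or cyclic loess. The mean deviation of the 22 iron genes from their own means was 0.06, -0.04, -0.20 and 0.17 on the log2 scale in replicates 1 to 4, that of the 17 inflammatory genes -0.11, 0.12, -0.20 and 0.19, and that of the 8 matrix genes 0.05, -0.07, -0.35 and 0.37. In replicate 4, 19 of the 22 iron genes, 13 of the 17 inflammatory genes and 8 of the 8 matrix genes were higher than in replicate 3, against 62.9% of all genes; the groups shared no gene. Replicate 3 was lowest in 14 iron, 9 inflammatory and 5 matrix genes, against 34.4% of all genes, and replicate 4 highest in 15, 10 and 4, against 36.3%. The same order of group means held in 6 groups that did not pass the test: macrophage, lysosome, cholesterol synthesis, glycolysis and hypoxia, ribosomal protein and housekeeping genes. Replicate 4 was also the array of lowest signal and had the most spots marked as outliers, 1.63%. The median deviation of all genes was 0.07 in replicate 4 and -0.03 in replicate 3. Among single members, Cxcl2 was at -0.33, 0.21, -0.72 and 0.45 in replicates 1 to 4, and Mmp12 at -2.10, -2.00, -1.86 and -0.29.

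Against 10000 random lists matched on level, 3 of 22 groups passed for shared movement, each with an adjusted permutation p of 0.0455 (unadjusted 0.0062 for iron, 0.0038 for inflammatory and 0.0051 for matrix genes). The SD of the mean deviation over the 4 arrays was 0.16 for iron genes, 0.18 for inflammatory genes and 0.30 for matrix genes, against medians of 0.06, 0.06 and 0.08 in random lists. Macrophage genes were at an adjusted permutation p of 0.0891, and the other groups lay between 0.185 for the inflammasome and 0.989. The 3 calls were close to the threshold and depended on the processing: 0 groups passed with quantile normalization, and 0 with the 75th percentile taken over probes above background on all arrays, a scaling often used where, as here, fewer probes are above background than below. The number was also 0 with the positive and significant mark, the mean over probes, or genes above background on at least 1 array. It was 0 without replicate 3, 1 without replicate 2 and 1 without replicate 4.

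**Figure D4:**
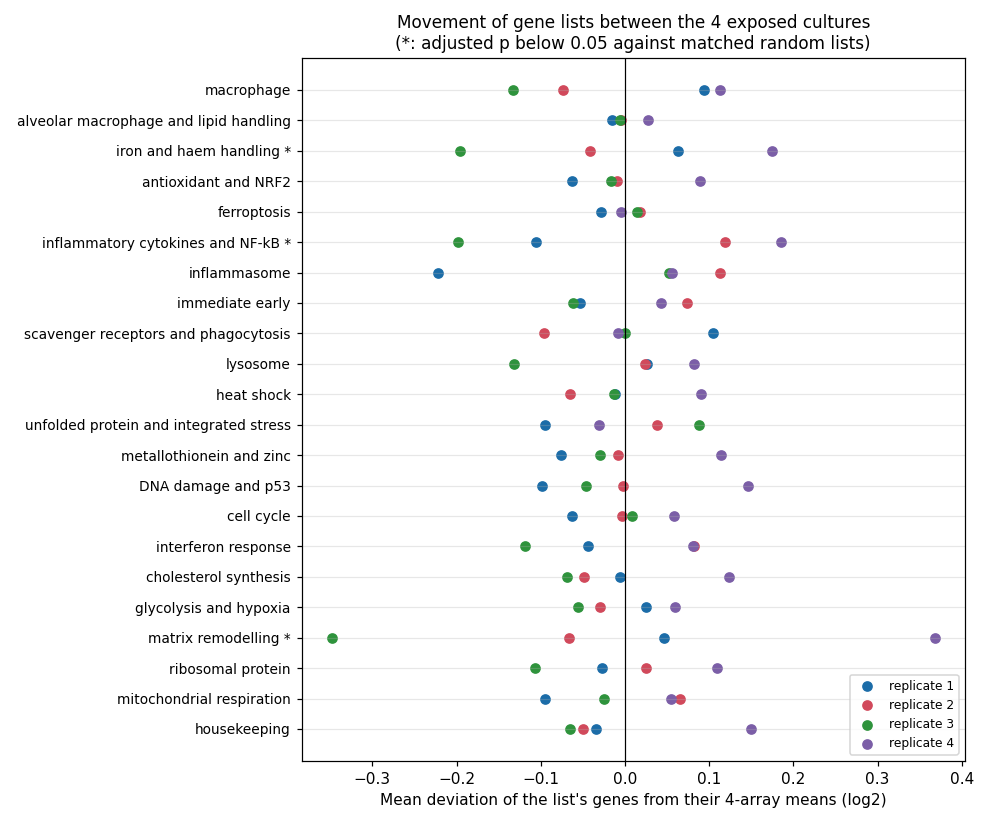
Mean log2 deviation of the members of each of the 22 tested gene groups from their own means, 1 coloured point per exposed array, with an asterisk for the 3 groups that passed the test of shared movement. In matrix remodelling, replicate 3 lay at -0.35 and replicate 4 at 0.37.

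For the median SD of members, 0 of 22 groups passed at the adjusted threshold against the matched random lists, and 3 had an unadjusted permutation p under 0.05: 0.0036 for matrix remodelling, 0.0274 for inflammatory genes and 0.044 for the unfolded protein and integrated stress responses. The median SD was 0.30 for matrix genes and 0.17 in matched random lists, with an adjusted permutation p of 0.0792. Without replicate 1, 2 groups passed.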

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

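The tests on bright spots in this part were chosen only after the result was seen. Of 121 sets of 4 values examined with Dixon's test, 17 had an array apart from the others, where chance gives about 1 in 20. Among the 10 genes of lowest adjusted p for excess spread 8 did, and 9 of the other 111 sets.

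In 8 genes a single array stood far above the other 3. Nek4 was at 5.92, Rnf44 at 4.01 and Grwd1 at 2.14 on replicate 2, Usp40 at 4.30 on replicate 1, and RGD1359108 at 5.84, Mgat1 at 5.36, Ccdc28b at 5.40 and Brca1 at 1.49 on replicate 4, on the log2 scale relative to the 75th percentile.

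Among probes with 1 spot per array, 40 spots exceeded the other arrays by more than 2 on the log2 scale at a level above the 75th percentile, and 29 of them lay within 10 rows and 3 columns of another on the same array, against a median of 2 and at most 10 in 10000 random placements. At any level, 690 spots exceeded the others by as much, and 548 lay that close to another, against at most 252 in 20 random placements. Other probes of the same genes that were above background on that array differed from their level on the others by a median of -0.30 on the log2 scale (6 probes, highest 0.61), which argues against higher expression in that culture for the 5 genes with such probes, of which Usp40 is among the 8 above. Debris or a scratch on the slide is a candidate explanation for the clustered spots. It stays open for RGD1359108 and Rnf44, whose spots lay apart from others, and no other biological explanation was tested.

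Replicate 4 had 1.63% of its spots marked as outliers, against 1.13% to 1.21% on the other arrays. The mean deviation of housekeeping genes was 0.15 in replicate 4 and -0.07 to -0.03 in the others, beside a median deviation of all genes of 0.07 in replicate 4.

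Among list genes, Lamp2 at 3.08, Mt2A at -2.11 and Mmp12 at -0.29 stood above the other arrays in replicate 4. Cathepsin B, Ctsb, at 6.51 and Rps3 at 6.85 stood below them in replicate 3. In replicate 1, Hsp90aa1 stood above the others at 5.24 and Sdha below them at 2.76.

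Outside the named genes, 6310 of 24489 probes without a symbol (25.8%) were above background on all 4 arrays. Of 96 ERCC control probes 1 was above background on all 4.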

How the results depend on the processing

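The streak alternative was chosen after seeing the data; all others were planned. The counts of genes above background and of groups differing in detection kept within 1.5 times under each alternative run, but single groups changed sides. Alveolar macrophage genes no longer passed with the positive and significant mark or with genes above background on at least 1 array (exact test adjusted p 0.0332 to 0.1 over the alternatives). Immediate early and granulocyte genes passed with both. Metallothionein genes and T and NK cell markers passed with the first, and inflammasome genes with the second. Granulocyte genes also passed without replicate 4 (exact test adjusted p 0.0474). Granulocyte genes and T and NK cell markers passed with a lower share. The inflammasome group gained only P2rx7, above background on 1 array. It was at -7.76, -3.86, -7.88 and -7.20 in replicates 1 to 4. Groups passing for shared movement numbered 3, and 0 with the 75th percentile over probes above background, quantile normalization, the positive and significant mark, the mean over probes, or genes above background on at least 1 array; they numbered 0 to 3 with 1 array left out, and 4 without bright streaks, where macrophage genes passed too (adjusted permutation p 0.0434). Over the 9 planned settings that keep all arrays, the adjusted permutation p ranged from 0.022 to 0.238 for iron genes, from 0.0022 to 0.238 for inflammatory genes and from 0.0301 to 0.238 for matrix genes. Groups passing for spread numbered 0, and 0 to 2 with 1 array left out (2 without replicate 1). Genes of excess spread numbered 16, and 156 with normexp, 5 with a constant prior, 10 with a prior that was not robust, 6 without bright streaks, and 7 to 22 with 1 array left out. The lowest Pearson's r between arrays across genes was 0.990, and 0.988 with normexp, 0.980 with genes above background on at least 1 array, and 0.989 to 0.992 with 1 array left out. The ratio of spread between arrays to spread within them was 2.06, 1.31 with normexp and 1.75 to 2.00 with 1 array left out. With 1 array left out, the SD of Grwd1 ranged from 0.10 to 1.995 and that of RGD1359108 from 0.0754 to 3.35; the lowest, without replicate 2 and without replicate 4, lay below that of genes of like level because the single bright spot was left out. The cause of the other shifts was not tested. No spot was saturated, so leaving out saturated probes moved nothing and has no value. Single-gene levels moved in 131 cases, 85 of them with the other percentile, whose reference level differs by construction. No paired analysis was possible because the samples form 1 group. Weak signal limits what is known of the 43.0% of genes above background on no array.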

Other observations

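Cyclic loess was a planned setting; its use here as a test of cause, and the tests of the innate secretory list without a member or with dimmer members, were chosen only after the result was seen. The ribosomal RNA probes Rn18s and Rn5-8s differed between the 4 arrays, with the same order of arrays. Whether the cultures or the arrays differed cannot be told apart, and the cause was not tested. Rn18s was at 3.16, 5.53, 4.03 and 4.22 in replicates 1 to 4 (limma adjusted p 0.00566) and, like Rn5-8s, was highest in replicate 2 and lowest in replicate 1. The precursor probe Rn45s, at 7.84 ± 0.25 (SD, n = 4), did not pass (limma adjusted p 0.952). The Y-linked genes Ddx3y, Eif2s3y and Uty were above background on no array. Named after their values were seen, the pattern recognition receptor Tlr2 lay at 1.95 ± 0.13, the C5a receptor C5ar1 at 1.31 ± 0.47 and the complement stabiliser properdin, Cfp, at 2.81 ± 0.12, all above background on all 4 arrays. The itaconate-producing enzyme Acod1, the pentraxin Ptx3 and haptoglobin, Hp, were above background on no array.

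Iron, inflammatory and matrix genes were each lowest in replicate 3 and highest in replicate 4 with the scaling to the 75th percentile, an order that 6 groups that did not pass shared. Without its most variable member, each group kept an unadjusted permutation p under 0.05, the bound set before the test. This argued against that 1 gene alone carrying the whole movement. It does not show a movement of the whole group, since the groups were chosen by their movement on these same arrays. The bound is also laxer than the adjusted threshold, and other variable members stayed in, such as Mmp9 (SD 0.80) and Ccl4 (SD 0.50). The unadjusted permutation p was 0.0321 for iron genes without Lcn2, 0.0065 for inflammatory genes without Cxcl2 and 0.00900 for matrix genes without Mmp12. For iron genes the SD of the mean deviation was 0.16 before and 0.11 after. Their 0.0321 lies above the unadjusted permutation p of 0.0162 of macrophage genes, which did not pass after adjustment. The adjusted call for iron genes therefore depended on Lcn2. The 3 groups shared 1 adjusted permutation p, 0.0455, set by the iron genes, whose unadjusted p was the highest of the 3. The calls for inflammatory and matrix genes thus depended on Lcn2 too. In the same way, all 3 calls depended on Mmp12. No adjusted p was computed without these members. After cyclic loess, which removes level-dependent differences between arrays, the unadjusted permutation p was 0.0066, 0.0052 and 0.0051 in the same order (adjusted permutation p 0.0499 each). No group passed after quantile normalization, which also evens out such differences. Whether level-dependent differences were the whole cause therefore cannot be decided from these settings. The mean deviation in replicate 4 was 0.17, 0.19 and 0.37 before loess and 0.10, 0.12 and 0.29 after, while the median deviation of all genes there was 0.07 before and 0.00 after. Position on the slide, the low signal of replicate 4, handling of each culture and chance stay open. Of the 9 planned settings that keep all arrays, 6 did not pass for iron genes and 5 did not for inflammatory or matrix genes. No biological explanation was tested for the movement of these groups.

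Lcn2 and Slpi, both secreted by activated innate immune cells, were lowest in replicate 3 and highest in replicate 4, and the second probe of Slpi gave -3.07, -3.42, -4.87 and -1.86 in replicates 1 to 4. The hypothesis that a wider innate secretory programme differed between the cultures was tested on a separate list, written before the test. It held 25 genes chosen as innate secretory and acute phase, none of them Lcn2 or Slpi. Chi3l1 was 1 of them and also in the alveolar macrophage group. Receptor genes such as Tlr2 and C5ar1 were on the list, so it did not hold genes of secreted proteins alone. For the 7 members above background on all 4 arrays the unadjusted permutation p was 0.195, with replicate 1 highest at 0.17; without Serping1 it was 0.232, with replicate 3 lowest at -0.14 and replicate 4 highest at 0.13. For the 13 members above background on at least 1 array, a choice that keeps genes such as C3 that lay below background in replicate 3, it was 0.326, with replicate 3 lowest at -0.26 and replicate 2 highest at 0.11, and without C3 it was 0.789, with an SD of the mean deviation of 0.10 against a random median of 0.16. None of these gave evidence for the hypothesis, and the bound set before the test against it, a p of 0.05 or more or another order of arrays, was met; that bound was too weak to exclude it, since a p that misses the threshold does not show that the 7 genes did not differ (SD of the mean deviation 0.12, random median 0.08) and their order of arrays turned on Serping1.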
